A study of Mus musculus with 8 samples.

How the data were processed

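Poly(A)-selected RNA libraries were made from F4/80-positive adipose tissue macrophages of 4 control and 4 knockout mouse samples, all after 20 weeks of high-fat diet, per the labels' protocols. Groups were taken from the genotype label of each sample and replicate numbers from its title. The labels call the samples biological replicates. They do not say whether each is 1 animal, so p-values measure the spread between these samples.

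The authors deposited a table of normalized gene counts with a column per sample, a signal that is never negative. The submitters' processing notes name FastQC, cutadapt, Salmon and DESeq2 and the genome build mm10, with no versions, roles or order. Each value is a whole number of reads divided by a single factor per sample: within a tolerance of 0.01 reads, 100% of the values came out whole. In control replicate 4 the step lies near 1, so that low values alone cannot tell it from rounding. The smallest value in each deposited column is 1 read, never 0. There are 26 genes at exactly 1 read in at least 4 samples, and all 26 exceed 20 reads in another. Whether 1 read was added to each count is not given in the sources used here. The authors also deposited a DESeq2 comparison, which holds, per the file headers, the mean signal, a log2 fold change of control over knockout (opposite in sign to the differences used here), its standard error and test statistic (score columns) and p-values. Its adjusted p is missing for 1558 genes and given for 14309.

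The table names 15867 genes, with a lowest mean of 9.35, and whether lower genes were removed before deposit is not given in the sources used here. There are 21 symbols that had turned into dates, 2 of them on 2 lines each, and none of these is named here. Gene positions came from GENCODE M21 on mm10, with 15640 names matched by symbol, 123 by synonym and 104 unmatched. Strand-specific counting is not given in the sources used here.

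The main test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), with eBayes with trend, for the 15862 genes with a mean of at least 10. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no covariate. As the deposited values are normalized, count models were used only as alternatives, on the recovered reads. A log2 difference on this scale understates the change of low genes. Recovered totals were 46621080, 36298146, 32667230 and 39096816 reads in control replicates 1 to 4 and 41495226, 31789395, 34603062 and 36582677 in knockout replicates 1 to 4. Normalized values near 10 stand for about as many reads, so genes at that level carry large counting error. Between libraries of a group, counts differed by far more than sampling noise (chi-square per gene of 8.86 or more), so all 8 were kept as separate replicates.

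Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 31 lists that have at least 5 measured members. Estimated correlation and fry were alternatives. List scores, the mean log2 value of the members, were compared by a two-sided exact permutation test over all assignments of 4 and 4 samples, whose smallest p of 0.0286 becomes 0.135 when adjusted over the lists. The lists covered macrophage states (lipid-associated, resident, monocyte, inflammatory cytokines, alternative activation, type I interferon, MHC class II), proliferation (S phase, G2/M phase, cell cycle brakes), lysosome, cholesterol efflux and synthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, ERK feedback, immediate early, heat shock, unfolded protein response and reported cluster targets. Others covered adipocyte, fibroblast and preadipocyte, mesothelial, endothelial and mural, T and NK cell, B cell, neutrophil, dendritic cell, eosinophil and mast cell, epididymal epithelium and erythroid genes. The test, the lists, the named-gene rule and all but the added alternatives were fixed before the data were examined; the general macrophage list was added after.

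Genes named in the text are those of the edited loci, the 10 highest and 10 lowest log2 differences among genes past the threshold with no overlap of groups (leaving out unnamed predicted and Rik genes), and for each list the 2 members with the smallest p and the most abundant one. Some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen. The numbers of genes at most 2 Mb from each locus were compared with the rest by two-sided Fisher exact tests.

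For seed sites, the longest annotated 3' untranslated region of each gene (at least 30 bases) was searched for the 8-base site of each family. Genes with the site were compared with genes lacking its 7-base core, in a linear model with log2 length and GC content. The reference was 200 words that permute the same bases. One-sided permutation p-values count words at or above the real site.

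Alternatives were pseudocounts of 0.5 and 5, other filters, 2 other scalings, other limma settings, array weights, a replicate block, leaving out each library, the authors' deposited table, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads, 7-base sites and no length and GC adjustment. Added after seeing the data were the removal of 1 read per value, edgeR on those reads and a covariate of endothelial and fibroblast markers. On the recovered reads edgeR called 556 genes, 545 of them among the 573 from limma, and DESeq2 1557, 571 of them shared. The limma step was tested on simulated data for knockout against control over 15862 genes: it recovered 37.3% of 67 genes changed by 1.5-fold, 65.7% of 67 changed by 2-fold and 81.8% of 66 changed by 3-fold, with 3 false calls among 126. In simulated data camera called 0 unshifted lists, and a miR-27 shift of 0.1 was estimated as 0.10. Each gene was drawn independently there, while list members varied together in the real data (estimated correlation 0.74 for S phase). The simulation thus cannot show how often camera calls such lists falsely. Figures were drawn with matplotlib 3.10.9.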

Results

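RNA was sequenced from macrophages that carry the surface protein F4/80 (encoded by Adgre1), selected from the adipose tissue of mice kept on a high-fat diet for 20 weeks. The 8 libraries form 2 groups of 4 biological replicates. All 8 samples came from mice with loxP-flanked alleles of Mirc11 and Mirc22, the microRNA clusters that encode members of the miR-23, miR-27 and miR-24 families. The control group had unmodified Lyz2 alleles. The knockout group carried the Lyz2-Cre knock-in on both alleles, which expresses Cre recombinase in myeloid cells and so deletes the clusters there. The labels do not state whether each replicate came from 1 mouse. The design asks which transcripts of adipose tissue macrophages differ when the clusters are lost. The groups differ in the clusters, in Cre and in Lyz2 at once, and no group carried Cre with intact clusters. Differences between the groups thus cannot be assigned to the clusters alone. The series title frames this around the proliferation of lipid-associated macrophages, the Trem2-positive cells that gather around dying adipocytes in obesity. Recovered read totals ran from 31789395 in knockout replicate 2 to 46621080 in control replicate 1. Values below are normalized gene counts, given as mean ± SD with n = 4 per group. Differences are knockout minus control of log2(normalized count + 1) from limma, with Benjamini-Hochberg adjusted p over 15862 genes.

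Lyz2, which encodes lysozyme M and holds the Cre knock-in, was almost lost from the knockout libraries. It measured 175874 ± 22446 in control and 208 ± 45.0 in knockout macrophages (log2 difference -9.73, SE 0.14, adjusted p = 2.86e-09). The lowest Lyz2 value among control libraries was 156727 and the highest among knockout libraries 273, so all 8 labels match the genotype at this gene. Its paralog Lyz1, encoded beside it, rose from 895 ± 78.5 to 3656 ± 1737 (1.92, SE 0.28, adjusted p = 0.0111), with 6016 in knockout replicate 1 and 2036 in knockout replicate 4. Lyz1 and Lyz2 transcripts share 34.2% of the 31-base words of Lyz1, so the split of reads between these genes is uncertain. Cpm, a membrane-bound carboxypeptidase of maturing macrophages, rose nearby, from 105 ± 19.1 to 210 ± 23.7 (1.00, SE 0.15, adjusted p = 0.0119). In mm10 coordinates, Lyz2 spans chromosome 10 from 117277331 to 117282321, Lyz1 117287797 to 117292868 and Cpm 117629500 to 117687352.

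The microRNAs of the clusters have no row in the deposited table, and their levels were not analysed here. Beside Mirc11, whose Mir23a lies on chromosome 8 at 84208518 to 84208592, Zswim4 (84210678 to 84237055) fell from 1417 ± 114 to 798 ± 57.9 (-0.83, SE 0.08, adjusted p = 0.00197). Adgre5, the leukocyte adhesion receptor CD97 (83723251 to 83741326), fell from 9312 ± 216 to 7099 ± 403 (-0.39, SE 0.05, adjusted p = 0.00804). Mirc22 lies within the annotated span of the aminopeptidase gene Aopep on chromosome 13 (62964893 to 63326096; Mir23b at 63300484 to 63300557). Aopep rose from 5995 ± 279 to 7793 ± 830 (0.37, SE 0.08, adjusted p = 0.0410), and Slc35d2 (64096308 to 64129368), a nucleotide sugar transporter, from 368 ± 22.0 to 475 ± 32.2 (0.37, SE 0.08, adjusted p = 0.0430). The calls of Aopep and Slc35d2 were lost in 7 and 8 of the 8 fits that left out 1 library. Apart from Lyz2, 2 of 23 measured genes within 2 Mb of Lyz2 passed the threshold, 2 of 69 around Mirc11 and 2 of 26 around Mirc22. No difference of these shares from that of genes elsewhere was detected by a two-sided Fisher exact test (p = 0.201, 1.00 and 0.241).

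**Figure D1:**
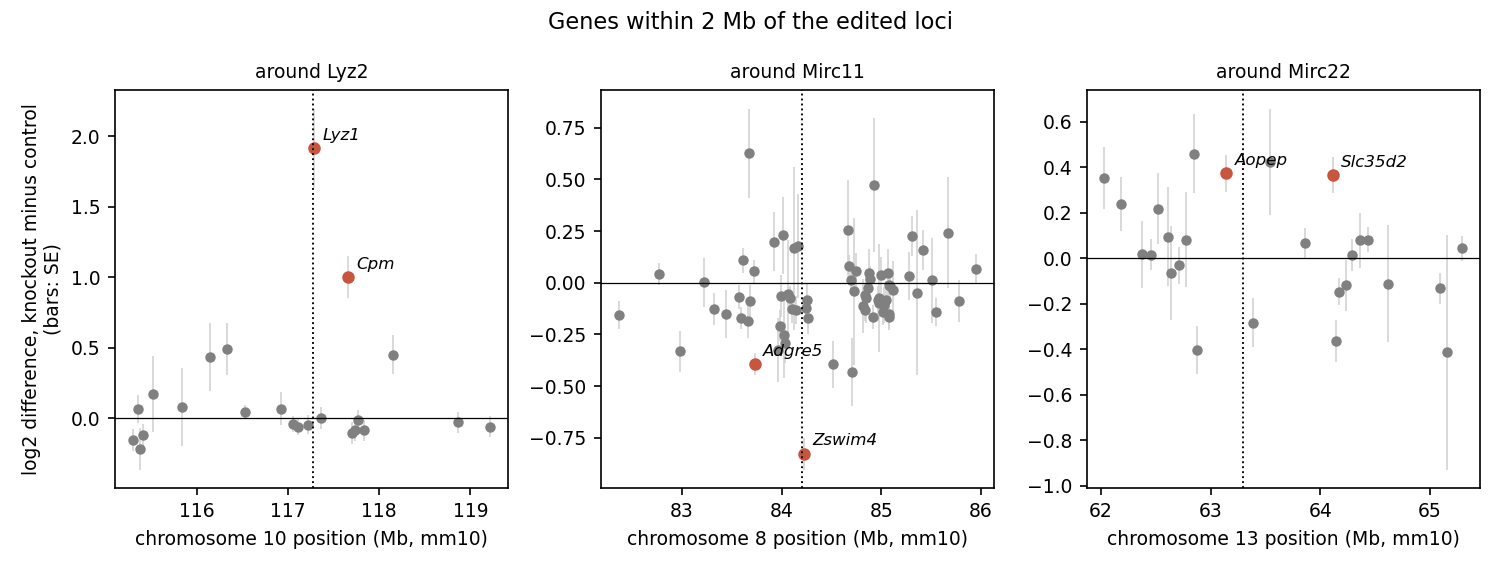
Log2 difference between knockout and control (y axis, bars: SE) against the gene midpoint in Mb (x axis, mm10) for genes within 2 Mb of Lyz2, Mirc11 and Mirc22 (dotted lines), with Lyz2 itself left out. Coloured, named points passed adjusted p under 0.05: Lyz1 and Cpm, Adgre5 and Zswim4, and Aopep and Slc35d2.

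Across the transcriptome 573 genes passed the threshold, 196 higher and 377 lower in knockout macrophages, and 52 of them (18 higher, 34 lower) differed by more than 2-fold. Among the genes that rose, Mmp10, a stromelysin, went from 17.4 ± 7.61 to 79.7 ± 11.9 (2.21, SE 0.30, adjusted p = 0.00789). The collagenase Mmp13 went from 284 ± 47.4 to 633 ± 62.3 (1.16, SE 0.13, adjusted p = 0.00367), and the arginine-degrading enzyme Arg1 from 165 ± 60.4 to 506 ± 138 (1.63, SE 0.26, adjusted p = 0.0146). The other named genes with the largest rises were the calpain Capn13 (2.06), the lectin-like ligand Clec2i (101 ± 30.4 to 283 ± 54.3), Spata25 (1.33), the secreted peptidase Pm20d1 (1.28) and the integrin subunit Itgad, known as CD11d (1.17). Pagr1a had the highest fitted rise (2.88, SE 0.65), but its 64.2 in knockout replicate 1 lay near the control range of 23.9 to 57.9, and its call was lost in 7 of the 8 fits that left out 1 library. Leaving out 1 library also ended the calls of Capn13 in 6 fits, Spata25 in 6 and Itgad in 5.

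Stac2, an adaptor of voltage-gated calcium channels, and Ctsk, the collagen-degrading lysosomal protease cathepsin K, were among the largest falls. Stac2 fell from 1497 ± 286 to 332 ± 42.2 (-2.16, SE 0.15, adjusted p = 0.000485), and Ctsk from 22883 ± 5434 to 5123 ± 600 (-2.13, SE 0.17, adjusted p = 0.00104). Coagulation factor VII, F7, fell from 2797 ± 270 to 881 ± 78.4 (-1.66, SE 0.09, adjusted p = 0.000122), and Vsig8 from 2896 ± 775 to 1046 ± 261 (-1.46, SE 0.22, adjusted p = 0.0138). F10, the gene of coagulation factor X, fell as well (-0.72, SE 0.13, adjusted p = 0.0258). The lowly expressed Plpp4 (-2.05, where the pseudocount understates its fall), Eef1a2 (-1.73), Myh3 (-1.71), Cyp4f39 (-1.63) and Lipn (-1.57) were the other named genes with the largest falls. Of these, the calls of Plpp4, Lipn and Eef1a2 were lost in 6, 3 and 2 of the 8 fits that left out 1 library.

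**Figure D2:**
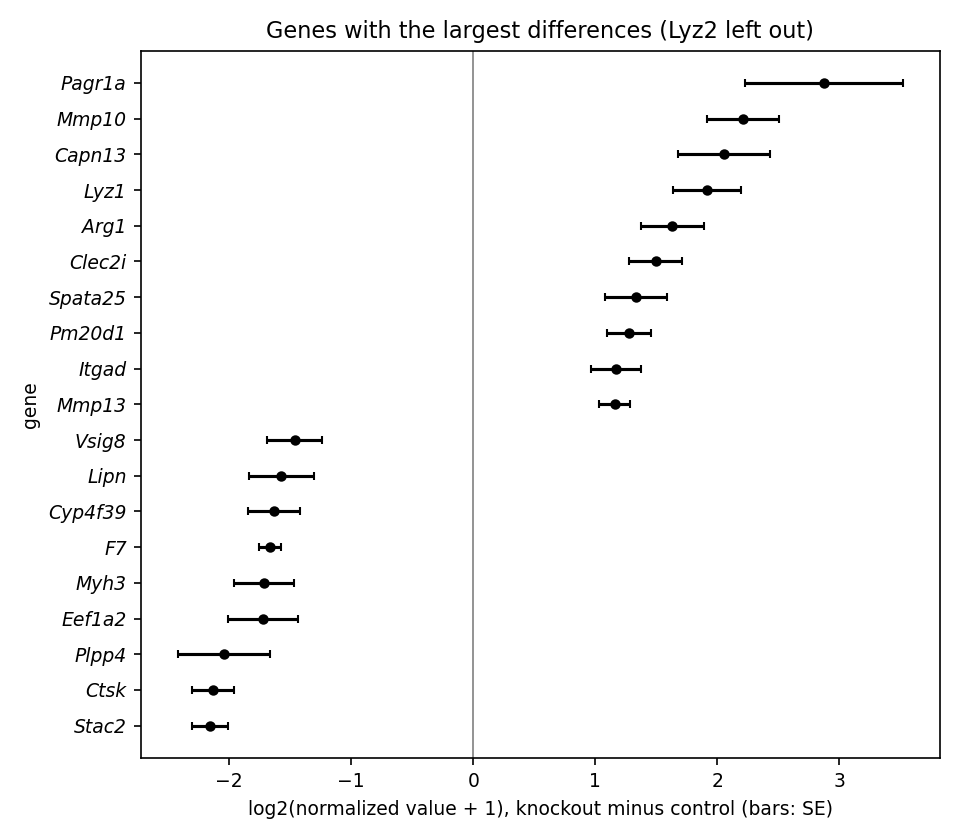
Log2 difference between knockout and control (x axis, bars: SE, n = 4 per group) for the named genes with the largest rises and falls (y axis). Pagr1a has the widest error bar (SE 0.65) and F7 the narrowest (SE 0.09); Lyz2 (-9.73) is left out to keep the scale readable.

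Knockout and control values did not overlap for 572 of the 573 genes, and for 2177 of all tested genes (13.7%, where chance gives 2.86%). Small unadjusted p-values were common too. Il15, chosen after its values were seen, had an unadjusted limma p of 0.0505 and an adjusted p of 0.237. A p under 0.05 was thus far more frequent over all genes than 0.05. Member counts at that p, given below, stand against this raised share, which was not counted, and those from DESeq2 against its 1557 calls. Scaling each library to the same total changed the balance of directions: it gave 245 higher and 244 lower genes (50.1% higher, against 34.2% as deposited) and moved the median of all genes from 0.00 to 0.06. The count was 376, 163 and 324 without control replicate 1, 3 or 4, and 210, 296, 241 and 237 without knockout replicates 1 to 4 in turn. The authors' deposited table lists 1557 genes at adjusted p under 0.05 (666 higher and 891 lower in knockout), 571 of which are among the 573.

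Transcripts of dividing cells showed no call as a group in the main test. Of 29 measured G2/M genes, which mark cells preparing for and passing through mitosis, 0 passed in limma, in edgeR and in DESeq2, and 0 had an unadjusted p under 0.05. The proliferation marker Mki67 measured 4102 ± 1000 in control and 3584 ± 430 in knockout (-0.17, SE 0.15, adjusted p = 0.565), and the cytokinesis gene Anln 776 ± 127 and 665 ± 63.0 (-0.21, SE 0.12, adjusted p = 0.339). The median member difference was -0.04 (camera adjusted p = 0.402; 0 members passed when adjusted over the list alone). Of 25 S phase genes 1 fell, E2f1, a transcription factor that drives entry into DNA synthesis, from 1673 ± 134 to 1342 ± 75.8 (-0.32, SE 0.07, adjusted p = 0.0447; also 1 adjusted over the list alone). Mcm3 (-0.22) and Pcna (-0.16) of the replication machinery did not pass (adjusted p = 0.187 and 0.352). The E2f1 call was lost in 7 of the 8 fits that left out 1 library. The S phase list had a median of -0.10 and camera adjusted p = 0.0786.

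These 2 lists turned on single libraries. Control replicate 1 scored highest in both (0.29 and 0.33 against at most -0.03 in the other controls). Without it the S phase list had adjusted p = 0.986 and the G2/M list 0.223. The S phase list passed as lower without control replicate 2, 3 or 4 (adjusted p = 0.0420, 0.0383 and 0.00609) or knockout replicate 3 (0.00209), and the G2/M list without control replicate 4 (0.0242) or knockout replicate 3 (0.0164). Both lists passed as lower with a covariate of endothelial and fibroblast markers (adjusted p = 0.002525 for S phase and 0.0001039 for G2/M). That covariate was -0.409 to -0.0794 in control and 0.115 to 0.266 in knockout libraries. As the groups did not overlap in it, fits with it extrapolate, here and below, and cannot show that proliferation fell. The same fit also turned the MHC class II list to higher (camera adjusted p = 2.75e-07). With an estimated correlation the adjusted p was 0.843 for S phase and 0.886 for G2/M. The exact permutation test of the list scores, two-sided, gave p = 0.457 and 0.714, where 4 against 4 samples can reach 0.0286. The list of cell cycle brakes (inhibitors of cyclin-dependent kinases, retinoblastoma family and antiproliferative genes) passed as lower with a median of -0.12 (camera adjusted p = 0.0277; adjusted p = 0.448 with an estimated correlation). Of its 20 members 0 passed in limma or edgeR and 3 passed as lower in DESeq2. An unadjusted p under 0.05 was found for 7, of which 6 were lower and 1 higher (0 passed when adjusted over the list alone). Cdkn2a, which encodes the inhibitor p16, measured 158 ± 24.5 and 96.5 ± 28.3 (-0.73, SE 0.21, adjusted p = 0.0983). Without control replicate 1 or knockout replicate 2 the cell cycle brakes list no longer passed (adjusted p = 0.0763 and 0.158), nor with a mean of at least 50 (0.0524), quantile normalization (0.0603) or array weights (0.101).

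Of 22 measured markers of lipid-associated macrophages 3 fell in the knockout group, 0 rose and 19 did not pass. Itgax, the integrin CD11c, fell from 28377 ± 3118 to 12601 ± 1532 (-1.17, SE 0.11, adjusted p = 0.00158). The lipid receptor Trem2 fell from 24953 ± 1998 to 18636 ± 1890 (-0.42, SE 0.09, adjusted p = 0.0388), and the actin-capping protein gene Capg from 30434 ± 2313 to 22783 ± 2217 (-0.42, SE 0.09, adjusted p = 0.0371). Apoe, the most abundant member, measured 454825 ± 93802 and 453756 ± 44124 (0.01, SE 0.18). Adjusted over the list alone, 6 fell. The list median was -0.22 (camera adjusted p = 1.14e-04; adjusted p = 0.448 with an estimated correlation), and the exact permutation p of its score was 0.0857. With quantile normalization the list had adjusted p = 0.0603. It shares 4 members with the lysosome list. The calls of Trem2 and Capg were lost in 8 and 7 of the 8 fits that left out 1 library.

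Of 18 general macrophage genes, a list drawn up after the data were seen, 5 fell. They were Csf1r, Cd68, Itgam, Mpeg1 and Msr1, while 13 did not pass and the median was -0.30 (exact permutation p of the score = 0.0286). Adjusted over the list alone, 12 fell. Csf1r, the receptor for macrophage colony-stimulating factor, fell from 64107 ± 5661 to 46860 ± 3996 (-0.45, SE 0.10, adjusted p = 0.0389). In the fits that left out 1 library its call was lost 7 times, that of Cd68 and Msr1 3 times each, and that of Mpeg1 without knockout replicate 1 (adjusted p = 0.0512). With a covariate of endothelial and fibroblast markers the difference of Csf1r was -0.14 (SE 0.20). The resident macrophage list was not called (median 0.11, camera adjusted p = 0.402): Cd209g, a lectin, rose (1.57, SE 0.36, adjusted p = 0.0491), Vsig4, a complement receptor, fell (-0.97, SE 0.15, adjusted p = 0.0148), and 18 members did not pass (3 higher and 1 lower when adjusted over the list alone). The resident macrophage list passed as higher without knockout replicate 4 (adjusted p = 0.0429) and with that covariate (adjusted p = 2.94e-04), with which the difference of Vsig4 was -0.09 (SE 0.17). Of 14 monocyte genes F10 fell and 13 did not pass, among them the chemokine receptor Ccr2 (-0.24, SE 0.06, adjusted p = 0.0598; list median 0.34, camera adjusted p = 0.182). Adjusted over the list alone, 6 monocyte genes were higher and 3 lower, and Ccr2 passed without control replicate 4 (adjusted p = 0.0414). The calls of Cd209g and F10 were lost in 7 and 5 of the 8 fits that left out 1 library.

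Of 20 measured cholesterol synthesis genes 7 fell, 0 rose and 13 did not pass, and 15 fell when adjusted over the list alone. Srebf2, the transcription factor that controls the pathway, fell from 5481 ± 129 to 3936 ± 207 (-0.48, SE 0.05, adjusted p = 0.00357), and Sqle, squalene epoxidase, from 809 ± 100 to 492 ± 24.3 (-0.71, SE 0.10, adjusted p = 0.00809). Lss, Cyp51, Dhcr7 and Fdps, chosen for naming after their values were seen, also fell; the calls of Lss, Cyp51 and Dhcr7 were lost in 6, 7 and 3 of the 8 fits that left out 1 library. The list median was -0.37, a fold of 0.772, with camera adjusted p = 1.13e-10 (adjusted p = 0.295 with an estimated correlation) and fry adjusted p = 0.0140. The list score was lower in all 4 knockout than in all 4 control libraries (exact permutation p = 0.0286, the smallest possible; 0.135 when adjusted over the lists, as for every list at this p), and so was the score of general macrophage genes. The cholesterol efflux list was not called (median 0.01, camera adjusted p = 0.570), but passed as higher with a covariate of endothelial and fibroblast markers (adjusted p = 0.0367). Of its 13 members Smpdl3a, a phosphodiesterase induced by liver X receptors, fell (-0.26, SE 0.05, adjusted p = 0.0403; lost in all 8 fits that left out 1 library). The desaturase Scd1 measured 1278 ± 138 and 1883 ± 382 (0.54, SE 0.14, adjusted p = 0.0772).

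Of 26 lysosomal genes 5 fell, 0 rose and 21 did not pass (10 fell when adjusted over the list alone). Besides Ctsk, the protective protein Ctsa fell from 36015 ± 1533 to 25819 ± 1243 (-0.48, SE 0.06, adjusted p = 0.00733). Ctss and Npc1, named after their values were seen, also fell, and their calls were lost in 8 and 7 of the 8 fits that left out 1 library. With a covariate of endothelial and fibroblast markers the difference of Ctss shrank from -0.55 to -0.06 (SE 0.24) and that of Ctsa was -0.34 (SE 0.15). That of Ctsk was -2.89 (SE 0.32, limma adjusted p = 0.0446), and the list kept its call (camera adjusted p = 5.50e-04). Ctsb, the most abundant member, measured 332497 ± 21561 and 264280 ± 18231 (-0.33, SE 0.13, adjusted p = 0.182). The median was -0.25 with camera adjusted p = 5.23e-08 (adjusted p = 0.448 with an estimated correlation), fry adjusted p = 0.0447 and exact permutation p = 0.0286. In the same libraries the mean score of general macrophage genes differed by -0.33 on the log2 scale.

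Oxidative phosphorylation had a median of -0.06 (camera adjusted p = 0.0127; adjusted p = 0.560 with an estimated correlation). Glycolysis and hypoxia had a median of -0.09 (camera adjusted p = 0.0129; adjusted p = 0.448 with an estimated correlation). In each, 0 of 25 members passed in limma or edgeR, with 2 and 4 lower in DESeq2. At an unadjusted p under 0.05 there were 3, all lower, and 8, of which 7 were lower and 1 higher. Such p-values were common over all genes, so these counts do not by themselves show an excess. The leading members by p were Sdhb of the respiratory chain (-0.22, SE 0.06) and the glycolytic enzyme Pgam1 (-0.27, SE 0.07), with adjusted p = 0.0832 and 0.0819; adjusted over the list alone, 0 passed in either list. The oxidative phosphorylation list no longer passed without control replicate 2 or knockout replicate 4 (adjusted p = 0.0560 and 0.0660), with the same total per sample (0.211), quantile normalization (0.365), array weights (0.131) or a covariate of endothelial and fibroblast markers (0.1475). The glycolysis and hypoxia list no longer passed without knockout replicate 2 (0.0569), with quantile normalization (0.111) or with array weights (0.101). Of 22 fatty acid oxidation genes 1 rose, also 1 when adjusted over the list alone. It was Ech1, a peroxisomal and mitochondrial dienoyl-CoA isomerase, which went from 5226 ± 200 to 6411 ± 289 (0.29, SE 0.05, adjusted p = 0.0211). Its call was lost in 5 of the 8 fits that left out 1 library. The fatty acid oxidation list was not called (camera adjusted p = 0.901). Its mean of -0.01 and its median of 0.00 differ in sign, the median and the test pointing higher.

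Of 21 measured interferon-stimulated genes 4 rose, 0 fell and 17 did not pass, with 9 higher when adjusted over the list alone. The antiviral gene Rsad2 (viperin) went from 977 ± 72.5 to 1386 ± 75.1 (0.51, SE 0.07, adjusted p = 0.00824) and Ifi44 from 146 ± 17.8 to 241 ± 29.4 (0.71, SE 0.13, adjusted p = 0.0248). Ifit1 and Oas2, named after their values were seen, were the others, and their calls were lost in all 8 fits that left out 1 library. The list median was 0.38, a fold of 1.30 (camera adjusted p = 2.39e-07; adjusted p = 0.448 with an estimated correlation and 0.0883 with fry), and the exact permutation p was 0.0571. In the same libraries the mean scores of T and NK cell genes and of endothelial and mural genes differed by 0.82 and 0.45 from control. The interferon list kept its call with a covariate of endothelial and fibroblast markers (camera adjusted p = 2.64e-09), a fit that extrapolates.

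Of 17 genes of alternative activation, the program that interleukin 4 induces in macrophages, Arg1 and Tgm2 rose, 0 fell and 15 did not pass (5 higher when adjusted over the list alone). The list median was 0.19, with camera adjusted p = 0.00190 (adjusted p = 0.295 with an estimated correlation), fry adjusted p = 0.0447 and exact permutation p = 0.0286. Tgm2, transglutaminase 2, went from 11250 ± 1432 to 15416 ± 1414 (0.46, SE 0.10, adjusted p = 0.0427), and the mannose receptor Mrc1 measured 42327 ± 4407 and 48255 ± 4935 (0.19, SE 0.10, adjusted p = 0.330). Among 21 inflammatory cytokine genes the monocyte chemoattractant Ccl2 rose from 805 ± 51.6 to 1328 ± 162 (0.72, SE 0.09, adjusted p = 0.00641). Ccl3 fell from 890 ± 265 to 389 ± 78.7 (-1.17, SE 0.21, adjusted p = 0.0234), and the list was not called (median 0.15, camera adjusted p = 0.549). The calls of Tgm2, Ifi44 and Ccl3 were lost in 7, 6 and 4 of the 8 fits that left out 1 library, and that of Arg1 without control replicate 3 (adjusted p = 0.0563). With a covariate of endothelial and fibroblast markers, which were higher in the knockout libraries, the difference of Tgm2 was 0.03 (SE 0.19), that of Ifi44 0.19 (SE 0.25) and that of Ccl3 -0.13 (SE 0.34). The inflammatory cytokines list passed as higher with that covariate (adjusted p = 7.90e-07) and without control replicate 4 (adjusted p = 0.0228); adjusted over the list alone, 2 of its genes were higher and 1 lower.

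Of 10 tested lists of other cell types 9 passed as higher in the knockout libraries by camera, and 0 of these with an estimated correlation or fry. The T and NK cell list had a median of 0.95 (camera adjusted p = 1.09e-04), the erythroid list 1.00 (0.00190), endothelial and mural genes 0.50 (5.45e-05), fibroblast and preadipocyte genes 0.35 (1.94e-04) and adipocyte genes 0.29 (4.06e-04). With an estimated correlation each of these lists had adjusted p = 0.448. In these 5 lists 0 members passed in limma or edgeR. By unadjusted p under 0.05 as higher there were 8 of 16 T and NK genes, 4 of 5 erythroid, 9 of 15 endothelial and mural, 7 of 15 fibroblast and 5 of 14 adipocyte genes, and DESeq2 called 1, 3, 4, 2 and 3 as higher. Adjusted over the list alone the counts were 5, 4, 6, 0 and 2 as higher. In the T and NK list each of these 3 counts also held 1 gene as lower, Il7r, with 5102 ± 674 and 3746 ± 635 (-0.45, SE 0.14, adjusted p = 0.106; DESeq2 adjusted p = 0.0224). The endothelial tight junction gene Cldn5 measured 7530 ± 2270 in control and 11880 ± 2398 in knockout (0.69, SE 0.22, adjusted p = 0.128). The fibrillar collagen gene Col3a1 measured 54903 ± 12241 and 75438 ± 18411 (0.45, SE 0.21, adjusted p = 0.248), and the adipokine gene Lep 365 ± 60.8 and 538 ± 59.0 (0.57, SE 0.13, adjusted p = 0.0515). In the control libraries Col3a1 thus stood near the level of Csf1r.

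Another 4 lists of other cells were called as well. B cell genes had a median of 0.51 (camera adjusted p = 0.0230; adjusted p = 0.663 with an estimated correlation) and dendritic cell genes 0.49 (0.0230; adjusted p = 0.448 with an estimated correlation). In both, 0 members passed in limma, edgeR or, for B cells, DESeq2, which called 2 dendritic cell genes as higher, and 1 and 3 had an unadjusted p under 0.05. Mesothelial genes had a median of 0.55 (camera adjusted p = 0.0127; adjusted p = 0.560 with an estimated correlation), and 1 of 12 rose, Upk1b, a uroplakin, from 21.2 ± 5.63 to 46.6 ± 6.67 (1.12, SE 0.22, adjusted p = 0.0328; 3 when adjusted over the list alone). Of 11 eosinophil and mast cell genes (median 0.94, camera adjusted p = 0.0127; adjusted p = 0.456 with an estimated correlation) the sialic acid-binding lectin Siglecf rose (1.13, SE 0.22, adjusted p = 0.0297) and the eotaxin receptor Ccr3 fell (-1.22, SE 0.19, adjusted p = 0.0148). The B cell list no longer passed without control replicate 2 or 3 or knockout replicate 1 (adjusted p = 0.163, 0.0653 and 0.311), nor the dendritic cell list without control replicate 1 or 2 or knockout replicate 1 (0.0791, 0.0782 and 0.0551). The mesothelial list no longer passed without knockout replicate 2 (0.137), nor the eosinophil and mast cell list without control replicate 1 (0.0509). With the same total per sample these 4 calls were lost too (0.0748 for B cell and dendritic cell, 0.0732 for mesothelial and 0.0653 for eosinophil and mast cell genes). The calls of Upk1b and Siglecf were each lost in 7 of the 8 fits that left out 1 library, and that of Ccr3 without control replicate 3 (adjusted p = 0.0517). The neutrophil list was not called (median 0.09, camera adjusted p = 0.402): of 8 genes 0 passed in limma or edgeR, 1 in DESeq2, 1 adjusted over the list alone and 1 at an unadjusted p under 0.05.

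**Figure D3:**
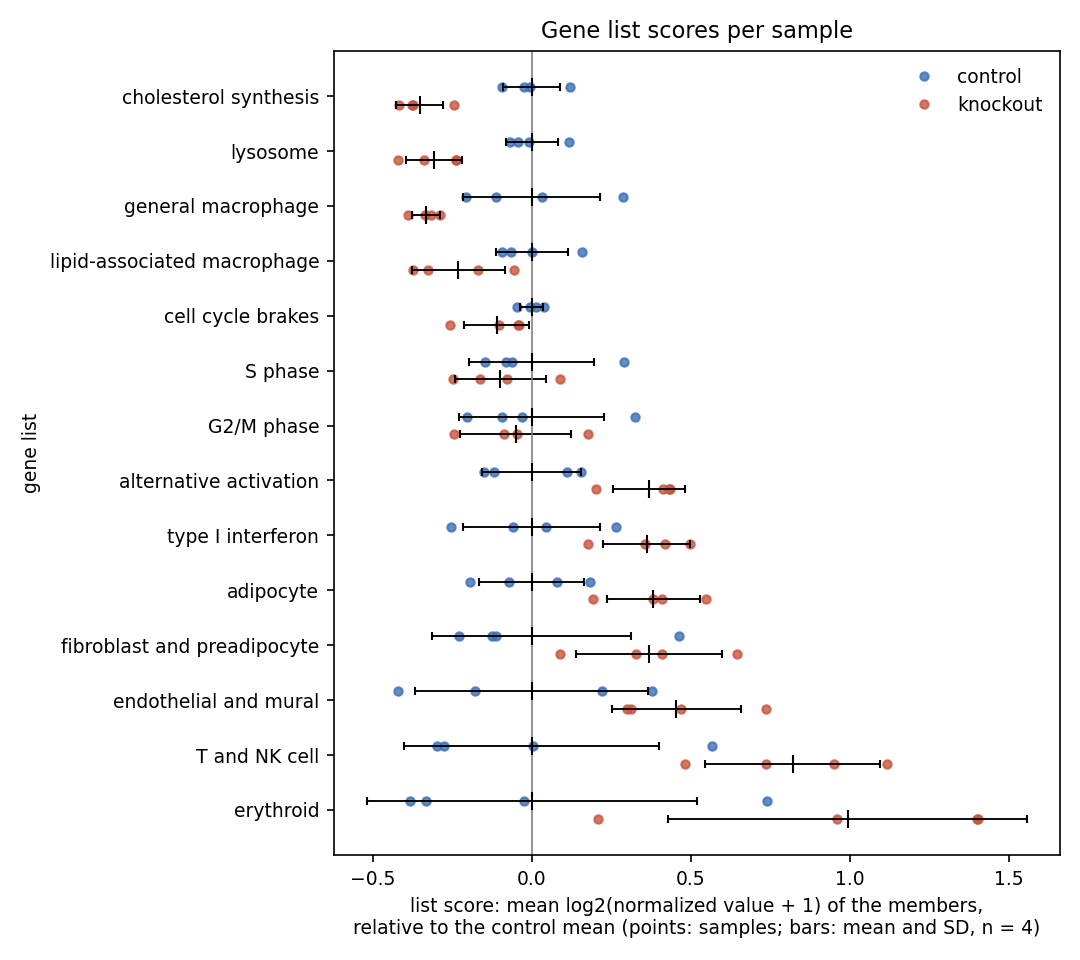
List scores per sample (x axis: mean log2(normalized count + 1) of the members relative to the control mean; points: samples; bars: mean and SD, n = 4) for 14 gene lists (y axis). Cholesterol synthesis, lysosome and general macrophage scores of all 4 knockout libraries lie below those of all 4 control libraries, while S phase and G2/M scores overlap.

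Predicted targets of the deleted microRNAs were slightly higher in knockout macrophages. Genes whose 3' untranslated region held the 8-base miR-27 site ACTGTGAA (960 genes) differed by 0.05 more than 12252 genes without the site, on the log2 scale and after adjustment for length and GC content of the region. Of 200 control words, permutations of the same bases, 0 reached this value, which gives a one-sided permutation p = 0.00498, the smallest this comparison allows. For the miR-23 site AATGTGAA (1061 genes) the difference was 0.04 and 2 of 200 words reached it (permutation p = 0.0149). Of these, TGTGAAAA (0.055) holds TGTGAA, which the miR-23 and miR-27 sites share, so these families are not fully separate tests. For the miR-24 site CTGAGCCA (1305 genes) it was 0.03 and 7 of 200 words reached it (permutation p = 0.0398). These comparisons run across genes, which are not independent replicates. The miR-24 value missed the threshold without control replicate 2 or 3 or knockout replicate 4 (permutation p = 0.0547, 0.0597 and 0.0597), with 7-base sites (0.0995), with a mean of at least 50 (0.0896) and with a covariate of endothelial and fibroblast markers (0.308). With that covariate the miR-23 value also missed it (permutation p = 0.0647).

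Genes with a site were also called as higher more often. Of genes with a miR-23 site 3.49% rose, against 1.13% without (two-sided Fisher exact p = 3.09e-08). The shares were 2.81% and 1.16% for miR-27 (Fisher exact p = 1.23e-04) and 2.07% and 1.20% for miR-24 (p = 0.0129). Shares of genes called as lower did not differ detectably (Fisher exact p = 0.469, 0.588 and 0.179). These tests treat genes as independent. Unlike the differences above, they and the shares that follow are not adjusted for length and GC content of the region. The share that rose was 0.977% of 11974 genes with none of the sites, 2.33% of 2571 with sites of 1 family and 4.08% of 343 with sites of 2 families. Of 23 genes with sites of all 3 families 1 rose, the mitotic kinase gene Nek6, which was chosen after its values were seen (0.48, SE 0.09, adjusted p = 0.0287), and 1 fell. The shares that fell were 2.46%, 2.45%, 2.92% and 4.35% of genes with sites of 0, 1, 2 and 3 families. Among 31 measured genes reported as targets of the clusters in other settings, 2 rose, 3 fell and 26 did not pass (3 higher and 3 lower when adjusted over the list alone), and the list was not called (median 0.05, camera adjusted p = 0.272). The histone variant gene H2ax, with miR-23 and miR-24 sites, rose from 697 ± 30.9 to 1097 ± 80.1 (0.65, SE 0.07, adjusted p = 0.00357). The adenosine receptor gene Adora2b, with a miR-27 site, rose from 140 ± 2.38 to 232 ± 19.8 (0.72, SE 0.10, adjusted p = 0.00764). Rel (-0.41), Tgfbr1 (-0.58) and Igf1 (-0.39), named after their values were seen, fell, and their calls and that of Nek6 were each lost in at least 6 of the 8 fits that left out 1 library. With a covariate of endothelial and fibroblast markers the difference was -0.15 (SE 0.17) for Rel, -0.18 (SE 0.20) for Igf1 and 0.20 (SE 0.20) for Nek6. That of Tgfbr1 was -0.57 (SE 0.29).

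**Figure D4:**
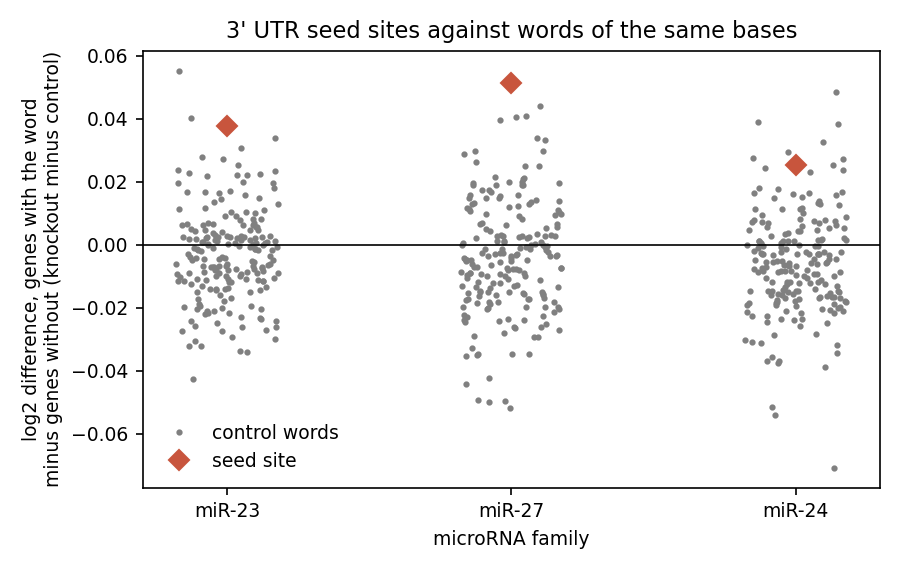
Difference in mean log2 change (knockout minus control) between genes with and without an 8-base word in the 3' untranslated region (y axis), for the seed site of each microRNA family (diamonds) and 200 control words of the same bases (dots). The miR-27 site (0.05) lies above all its control words, 2 words lie above the miR-23 site and 7 above the miR-24 site.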

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

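All tests weighed in this part were chosen after the results were seen. A library was singled out where its gap to the nearest of the other 3 libraries of its group as a share of the group's range exceeded Dixon's 95% critical value. This held in 17 of 256 groups of 4 values, where chance gives about 1 in 20, or 12.8.

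Control replicate 1 stood apart in proliferation genes. Its Pcna was 10680 against 8262 to 8609 in the other control libraries, and its Mcm3 3137 against 2694 to 2713. Tgfbr1 was 6784 there against 4952 to 5096, Cyp4f39 210.4 against 130.7 to 137.8, and the fibroblast and preadipocyte score 0.4638 against -0.2272 to -0.1116. Its mitochondrial share of the values was 2.263% against 1.719% to 1.8%.

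Control replicate 4 stood apart in antigen presentation genes. Its MHC class II score was 0.9086 against -0.3917 to -0.2273 in the other controls. Vsig4 was 1690 there against 1064 to 1151, Cpm 133.8 against 95.48 to 95.77, and Scd1 1073 against 1326 to 1374. In control replicate 2 Npc1 was 7825 against 8454 to 8538, and in control replicate 3 the oxidative phosphorylation score was -0.05722 against 0.0122 to 0.02515.

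Among knockout libraries, replicate 1 had Ighm at 23140 against 9164 to 10550 and Ctsk at 4227 against 5347 to 5473. Replicate 3 had the cytotoxic granule gene Gzma at 173.2 against 50.97 to 57.14. Replicate 4 had Ccr3 at 139.6 against 104.4 to 108.4 and the alternative activation score at 0.2007 against 0.4129 to 0.4336.

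The lipid-associated macrophage, lysosome and cholesterol synthesis lists passed as lower by camera and 9 lists of other cell types as higher, none of them with an estimated correlation (adjusted p = 0.448, 0.448 and 0.295 for the lower lists; 0 of 31 lists called), and a lower share of macrophage RNA could give this. With the other-cell score (the mean log2 value of endothelial, mural, fibroblast and preadipocyte markers) as covariate, the difference of the general macrophage score went from -0.3325 (SE 0.1094) to 0.1618 (SE 0.1452). That of cholesterol synthesis went from -0.352 (SE 0.0580) to -0.5062 (SE 0.1297) and that of T and NK markers from 0.8211 (SE 0.2434) to 1.661 (SE 0.4763), both beyond 2.57 SE. The lipid-associated list went from -0.2308 (SE 0.0925) to -0.4331 (SE 0.2181) and the lysosome list from -0.3075 (SE 0.0603) to -0.3185 (SE 0.1562), both within 2.57 SE of 0. The covariate was -0.409 to -0.0794 in control and 0.115 to 0.266 in knockout libraries, with no overlap, which widens these errors. The fit thus extrapolates from slopes within the groups. There, the fibroblast and endothelial parts of the covariate often moved in opposite directions. They were 0.46 and -0.42 in control replicate 1 and -0.12 and 0.38 in control replicate 2. In knockout replicates 1 and 3 they were 0.09 and 0.74, and 0.64 and 0.30. Control replicate 4 was low in both (-0.23 and -0.18). The covariate may therefore not track the share of other cells within a group. The slope was -2.04 (SE 1.05) for T and NK markers and 0.37 (SE 0.29) for cholesterol synthesis, each opposite in sign to what a lower macrophage share would give. The fit therefore cannot decide, and a lower share stays open for all of these lists. T and NK markers minus fibroblast markers differed by 0.4526 (SE 0.3809, exact permutation p = 0.2857), too wide to show whether other cell types rose alike, although F4/80 selection is meant to remove such cells and Col3a1 was near Csf1r in level. An effect of the deleted clusters, of Cre or of the loss of Lyz2 within macrophages stays open for all of these patterns. So does a change in T and NK cells themselves.

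Genes beside the edited loci changed, Lyz1 and Cpm near Lyz2 among them. Sequence linked to the Cre knock-in may differ between the groups, but within 5 Mb of Lyz2 2 of 44 genes passed (4.55%, against 3.61% elsewhere; two-sided Fisher exact p = 0.673), too few to decide. Linked sequence, the inserted Cre, the loss of Lyz2 and an effect of the deletion cannot be told apart here for Lyz1 and Cpm. The genes near Mirc11 and Mirc22 lie on other chromosomes than the knock-in.

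Lyz1 rose where Lyz2 was lost. Lyz1 reads counted as Lyz2 in control libraries may have lowered Lyz1 there, as 34.23% of the 31-base words of Lyz1 transcripts occur in Lyz2. The remaining words do not occur in Lyz2, so with even coverage most Lyz1 reads could still be told apart, while Lyz1 rose 4.09-fold. If coverage was even, which was not examined, this argues against misassigned reads as the whole cause of the rise. It leaves them open as a part of it.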

How the results depend on the processing

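The other-cell covariate and the removal of 1 read were chosen after the data were seen. Of 93 named genes and 31 lists, all kept direction and side of the threshold with a pseudocount of 0.5, a mean of at least 1, no filter or 1 read removed. As the lowest mean was 9.35, a mean of at least 1 and no filter are the same fit. It holds 15867 genes instead of 15862, so little change was possible there. Without trend 292 genes passed (115 higher, 177 lower), with array weights 931 (397 higher), and in the authors' deposited table and with DESeq2 on recovered reads 1557 each (666 higher, 891 lower). With the same total per sample 244 were lower. Without 1 library, where fewer samples enter, the counts ran from 163 to 502 (51 to 189 higher, 112 to 313 lower), the adjusted p of the S phase list from 0.002092 to 0.9862, that of the G2/M phase list from 0.0164 to 0.7846 and the miR-24 difference from 0.02332 to 0.02728. The lipid-associated macrophage list had adjusted p = 0.06028 with quantile normalization, 0.4482 with an estimated correlation and 0.1094 with fry. The miR-24 difference was 0.01889 with a mean of at least 50 (permutation p = 0.0896) and 0.008795 with 7-base sites (p = 0.0995). With the other-cell covariate 5 genes passed (1 higher, 4 lower). Of the 573 genes 567 kept their sign and 360 at least 0.8 of their difference, while 94 kept less than 0.5 of it; the median ratio of differences was 0.930 and that of standard errors 2.41. Itgax went from -1.17 (SE 0.11) to -1.33 (SE 0.26) and Srebf2 from -0.48 (SE 0.05) to -0.49 (SE 0.13). Of 65 named genes called, 11 kept less than 0.5: Vsig4 went from -0.97 (SE 0.15) to -0.09 (SE 0.17), Tgm2 from 0.46 (SE 0.10) to 0.03 (SE 0.19), Ctss from -0.55 (SE 0.12) to -0.06 (SE 0.24) and Ccl3 from -1.17 (SE 0.21) to -0.13 (SE 0.34), and Ifi44, Csf1r, Slc35d2, Rel, Nek6, Igf1 and Msr1 also shrank. With the other-cell covariate, which did not overlap between the groups, the S phase list (adjusted p = 0.002525) and the G2/M phase list (0.0001039) passed as lower. The miR-23 and miR-24 differences were 0.04928 (permutation p = 0.0647) and 0.01647 (p = 0.308). There the resident macrophage (0.0002938), inflammatory cytokines (7.899e-07) and cholesterol efflux (0.03668) lists passed as higher. The MHC class II list (2.747e-07) and the immediate early list (0.0008314) turned to higher and the endothelial and mural list (0.5781), part of the covariate itself, to lower. The adipocyte, fibroblast and preadipocyte, eosinophil and mast cell and erythroid calls were also lost, and with a mean of at least 50 the mesothelial one. Apart from fewer samples and wider errors, the cause was not tested. With the replicate block 7 genes passed (0 higher in limma, 7 lower), 62 of 93 named genes lost their call and 31 of 31 lists kept theirs. Same-numbered samples share only a number: the correlations of their deviations were -0.200, -0.199, -0.0360 and -0.293, and no sample correlated best with its own number. The robust setting has no list values, since camera has no such version. Counting error limits genes near a mean of 10.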

Other observations

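The splits of the samples and the tests of gene lists against them were chosen after the results were seen.

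Stress and signalling lists were not called. Sesn2, a stress-induced regulator of nutrient signalling, rose from 389 ± 25.2 to 590 ± 18.02 (0.60, SE 0.07, limma adjusted p = 0.00526). It was the 1 called gene of 20 in the unfolded protein response list (also 1 adjusted over the list alone), whose median of -0.01 and mean of 0.01 differ in sign, with the test pointing higher (camera adjusted p = 0.738). Spry1 and Spry4, feedback inhibitors of the ERK pathway, measured 1632 ± 141 and 1971 ± 105, and 480 ± 79.9 and 668 ± 71.2 (limma adjusted p = 0.0720 and 0.0828). Of 18 ERK feedback genes 0 passed in limma or edgeR, 3 were higher in DESeq2 and 2 were higher adjusted over the list alone (median 0.17, camera adjusted p = 0.184, exact permutation p = 0.0286). An unadjusted p under 0.05 was found for 5, of which 4 were higher and 1 lower. The immediate early list (median -0.07, camera adjusted p = 0.412) and the heat shock list (median 0.04, camera adjusted p = 0.402) had 0 of 17 and 0 of 12 genes past the threshold in limma and edgeR, and 0 and 1 in DESeq2. At an unadjusted p under 0.05 they had 2, all lower, and 3, of which 2 were higher and 1 lower. Such p-values were common over all genes. Neither these counts nor the 5 of the ERK feedback list by themselves show an excess. Without control replicate 1 the immediate early list passed as lower (adjusted p = 0.0333) and the heat shock list and the unfolded protein response list as higher (0.0462 and 0.00900).

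Antigen presentation differed more between libraries than between groups. H2-Ab1, a chain of MHC class II, was 158654 in control replicate 4 and 52822 to 64317 in the other controls. Of 11 MHC class II genes 0 passed in limma, edgeR or DESeq2 and 0 had an unadjusted p under 0.05 (median -0.49, camera adjusted p = 0.272). Adam7, a gene of epididymal epithelium, varied within both groups: 527 and 101 in control replicates 3 and 4 and 1047 in knockout replicate 2, against 2.46 to 13.2 in the other libraries. The epididymal list had 2 measured genes and so no set test (median -0.14). Krt8, an epithelial and mesothelial keratin chosen after its values were seen, ran from 5.06 in knockout replicate 4 to 916 in knockout replicate 2.

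The 8 samples can be split into 4 and 4 in 35 ways. The real split gave 573 genes and the highest other 4. In the direction with more genes, which was lower in the real split, the counts were 377 and 3. In the direction with fewer genes, higher in the real split, they were 196 and 1. In each case 1 of 35 splits was as large and chance is excluded at 0.05. The same 1 of 35 held for the site differences, taken without sign, of miR-23 (0.03773, highest other 0.02942), miR-27 (0.05129 and 0.03575) and miR-24 (0.02527 and 0.01845). It held for the unadjusted camera p of the lysosome list (3.377e-09, best other 1.666e-08) and the cholesterol synthesis list (3.647e-12 and 1.209e-11), but these were counted for many lists, and the same share, 0.0286 and the smallest possible, becomes 0.135 for list scores when adjusted over the lists, so after such an adjustment chance is not excluded for these lists.

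By the camera p, chance was not excluded for the other lists before adjustment either. The scores of the alternative activation, glycolysis and hypoxia, and adipocyte lists did reach an exact permutation p of 0.0286, which becomes 0.135 when adjusted over the lists. As small an unadjusted camera p came from 22 of 35 splits for S phase (0.04565, best other 1.552e-15), 30 for G2/M phase (0.3373 and 8.46e-20), 10 for cell cycle brakes (0.01519 and 0.0002335) and 7 for lipid-associated macrophage genes (2.197e-05 and 1.099e-08). It came from 2 splits for alternative activation (0.000597 and 8.237e-05), 6 for type I interferon (2.315e-08 and 1.258e-16), 11 for oxidative phosphorylation (0.004647 and 7.53e-08) and 6 for glycolysis and hypoxia (0.005845 and 0.0001326). Among other cells it came from 3 splits for adipocyte (0.0001048 and 4.243e-07), 11 for fibroblast (4.376e-05 and 1.338e-18), 13 for mesothelial (0.00492 and 3.733e-07) and 9 for endothelial genes (7.029e-06 and 1.166e-11). The counts were 5 for T and NK cell (1.766e-05 and 1.061e-09), 19 for B cell (0.0115 and 1.279e-14), 9 for dendritic cell (0.0119 and 8.777e-05), 12 for eosinophil and mast cell (0.005329 and 8.576e-11) and 8 for erythroid genes (0.0006126 and 4.456e-13). Such small values in splits that mix the genotypes show that these lists also vary together between libraries of a group.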
